A study of Arabidopsis thaliana with 18 samples.

How the data were processed

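RNA-seq was measured in 18 libraries of whole Arabidopsis thaliana seedlings, 3 biological replicates, per the labels, in each of 6 groups. The groups were wild type (WT, Col-0), the mutants gbpl3-5, crwn4-1 and crwn1-1crwn4-1, and 2 transgenic lines in the gbpl3-5 background. The line comp2 carried the genomic GBPL3 fused to GFP under its own promoter. The line K83A carried the same construct with the K83A substitution. The reference protein has K at position 83. Seedlings were harvested 4 days after germination, after 2 days of stratification at 4 °C and growth under 16 h light and 8 h dark at 22 °C on medium with 2% sucrose, per the labels. Libraries were made from poly(A) RNA and sequenced as paired reads of 150 bp, per the labels' protocols.

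The deposited per-library tables hold estimated counts (reads per transcript) from Salmon, per the file headers and values that are not whole numbers. The same deposited tables hold TPM for each transcript, per the file headers. The deposited table of normalized counts holds a signal per gene that the authors scaled. Its nonzero values equalled, within 0.1% for 100% of them, the estimated counts summed per gene and divided by a size factor of the library and a relative length. The relative length is the gene's average effective transcript length in the library over its geometric mean across libraries. The submitters' processing notes name FastQC 0.11.9, MultiQC 1.12, Salmon 1.9.0, R 4.2.0, DESeq2 without a version, and the build TAIR10. The transcript set and the settings are not given in the sources used here. A deposited FPKM table was not used, because each gene's value was a constant multiple of its value in the table of normalized counts.

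Estimated counts of 48268 transcripts were summed to 27586 genes by identifier and rounded. Library totals ran from 24.1 to 37.2 M estimated reads (1 M is 1e6). Gene symbols, descriptions and positions came from the annotation of the TAIR10.1 assembly, which held 27389 of the 27586 genes. Its transcript lengths were compared with those in the deposited tables, and 48071 transcripts were found in both, of which 99.6% had the same length. Positions printed are those of TAIR10.1. The reference gives CRWN1 and CRWN4 as LINC1 and LINC4, and the names of the labels are used here. Salmon divides reads among similar transcripts, so values of near-identical gene copies are uncertain.

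Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group, and 1 fit of all 18 libraries with group as the only factor. The filter kept 20714 genes, and the common biological coefficient of variation was 29.7%. P-values were adjusted by Benjamini and Hochberg over the 20714 genes within each of 10 comparisons, and a gene was called changed at an adjusted p under 0.05. Levels are CPM scaled by TMM, given as mean ± SD with n = 3. In the smallest library, of 24.1 M estimated reads, a level of 1 CPM stands for close to 24.1 reads before TMM scaling. Errors between replicates include counting error.

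For 23 gene lists, camera (limma 3.58.1) compared the members with the other genes, with its preset correlation of 0.01 between genes, and p-values were adjusted over the 23 lists of each comparison. Counts of called members are given over all genes and adjusted over the list alone. The lists are salicylic acid and defence, jasmonate response, heat shock, endoplasmic reticulum stress, DNA damage response, nuclear lamina and envelope, Polycomb-repressed developmental regulators, seed maturation, photosynthesis, mitosis, DNA replication, auxin response, abscisic acid and cold response, iron deficiency response, copper homeostasis, flavonoid and anthocyanin synthesis, triterpene gene clusters, root hair, root meristem, root endodermis and suberin, stomatal lineage, pericentromeric genes (within 3 Mb of a centromere position on TAIR10.1) and transposable element genes. NDC1 was left out of the nuclear lamina list because the reference gives that symbol to another gene.

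The comparisons, the tests, the 23 lists and the rule for named genes were fixed before the data were examined. The rule names the 3 targeted genes; per comparison and list, up to 4 called members with the smallest p; and, for comparisons with WT and for K83A with comp2, the 10 raised and 10 lowered genes with the largest fitted change among called genes whose 3 values all lay above or below the 3 of the other group, with a mean of at least 5 CPM in the higher group. Genes outside this rule are named with the words that they were chosen after their values were seen. Lists of 40 genes raised by low oxygen and of 18 circadian clock genes (9 of the morning and 9 of the evening), and the tests that use them, were chosen after the data had been seen.

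Alternatives fixed at the same time were RLE scaling, DESeq2 1.42.0, fits of the compared groups alone, the replicate number as a block, no filter, an offset for transcript length, limma-trend on the deposited normalized counts plus a pseudocount of 1, a minimum absolute log2 fold change of 1, an estimated correlation between genes, fry, and each library left out in turn. The removal of trends with transcript length and GC content (a spline with 5 degrees of freedom per library, the 1 form tried) and the joint omission of gbpl3-5 replicate 3 and comp2 replicate 2 were added after the data had been seen. The labels number the replicates of every group from 1 to 3. Libraries of the same number deviated together, with all 3 correlations of their deviations from the group means over 0.1, in 3 of 15 pairs of groups, namely gbpl3-5 with crwn4-1 (lowest 0.188), gbpl3-5 with crwn1-1crwn4-1 (lowest 0.129) and crwn4-1 with crwn1-1crwn4-1 (lowest 0.128). That pairing comes from the values and not from the labels. Unchanged groups and a WT group that they share were simulated 20 times, with genes drawn independently, since the 5 comparisons with WT share these controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and numpy 2.4.6 was used.

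The test was tried on counts simulated for all 18 libraries, from gene means pooled over the 6 groups and from the library sizes. Changes were put into the simulated gbpl3-5 group. The changed genes were drawn from genes above a set mean count, so recovery of genes with few counts was not measured. Genes were drawn independently, so trends between libraries, such as that with transcript length, were left out. With 200 genes changed 2-fold among 20544, 26.5% were recovered with 3.64% false calls. With 200 genes changed 4-fold among 20559, 94% were recovered with 5.05% false calls. With no gene changed among 20548, 0 were called.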

Results

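The transcriptome of whole seedlings was compared among WT, 3 mutants of putative components of the plant nuclear lamina, and 2 transgenic lines. GBPL3 is a guanylate-binding protein, and CRWN1 and CRWN4 are coiled-coil proteins of the nuclear periphery. Each of the 6 groups held 3 libraries. Their totals, in M estimated reads (1 M is 1e6), ran from 26.2 to 27.4 in WT, from 27.1 to 37.2 in gbpl3-5, from 26.2 to 27.3 in comp2, from 24.1 to 26.5 in K83A, from 26.3 to 30.0 in crwn4-1 and from 26.2 to 33.2 in crwn1-1crwn4-1.

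GBPL3 was lower in each gbpl3-5 library than in every library of the other groups. CRWN1 and CRWN4 were likewise lower in each library of their mutants. These levels cannot tell WT, comp2 and K83A libraries apart. GBPL3 (AT5G46070; TAIR10.1 chromosome 5, 18683319 to 18688822, 14 exons) had 57.3 ± 15.4 CPM in WT (mean ± SD, n = 3) and 11.2 ± 1.59 CPM in gbpl3-5, which is 19.6% of the WT mean. Its log2 fold change between these groups was -2.35 (SE 0.319, edgeR adjusted p = 0.000771). It stood at 56.4 ± 27.4 CPM in comp2, where replicate 2 had 24.7 CPM, and at 73.4 ± 5.44 CPM in K83A. CRWN1 (AT1G67230; chromosome 1, 25151211 to 25156389, 8 exons) had 66.3 ± 12.8 CPM in WT and 6.17 ± 1.72 CPM in crwn1-1crwn4-1. CRWN4 (AT5G65770; chromosome 5, 26311311 to 26316025, 10 exons) had 35.4 ± 8.63 CPM in WT, 4.91 ± 1.66 CPM in crwn4-1 and 3.48 ± 0.479 CPM in crwn1-1crwn4-1.

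**Figure D1:**
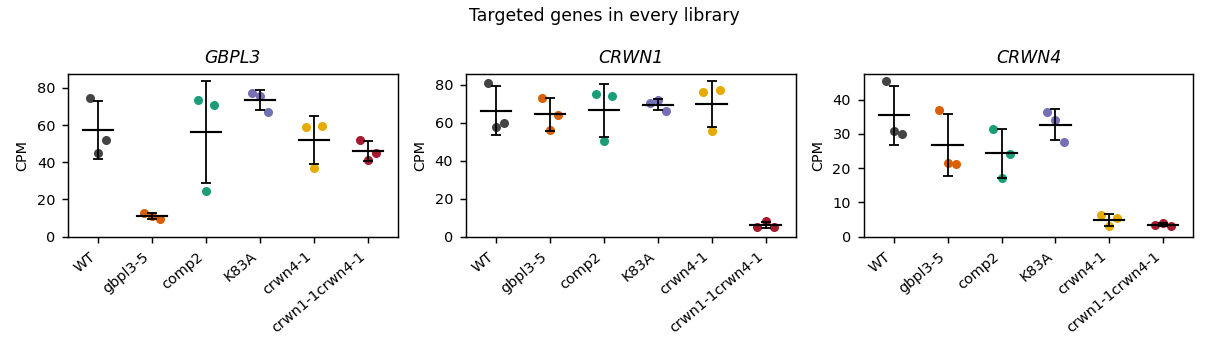
CPM (TMM-scaled) of GBPL3, CRWN1 and CRWN4 in each of the 18 libraries; points are libraries, horizontal lines are group means and bars are SD (n = 3). GBPL3 averaged 11.2 CPM in gbpl3-5 against 57.3 in WT, and CRWN4 averaged 4.91 in crwn4-1 against 35.4 in WT.

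Libraries also differed in other measured traits, some within the groups and some between them. Spearman's rho between a gene's transcript length and its deviation from the all-library mean, across genes that are not independent replicates, ran from 0.428 in gbpl3-5 replicate 1 to -0.526 in comp2 replicate 2, with -0.486 in gbpl3-5 replicate 3. The library comp2 replicate 3 lay farthest out on the first principal component (score 100.91). Transcripts of the 10 listed seed maturation genes, which are storage and late embryogenesis genes, summed to 269.7 CPM in comp2 replicate 2 and to at most 9.07 CPM in each of the other 17 libraries. Photosynthesis genes took 10.7% to 13.1% of the reads in WT, 14.6% to 19.5% in gbpl3-5, 16.1% to 19.9% in comp2, 12.9% to 15.8% in K83A, 14.5% to 17.3% in crwn4-1 and 10.9% to 13.3% in crwn1-1crwn4-1. Malate synthase (MLS), an enzyme of the glyoxylate cycle that young seedlings use on stored lipid, had 80.5 ± 39.0 CPM in WT, 36.6 ± 28.04 CPM in gbpl3-5, 13.4 ± 6.99 CPM in comp2, 76.7 ± 49.95 CPM in K83A, 16.4 ± 8.88 CPM in crwn4-1 and 95.1 ± 16.1 CPM in crwn1-1crwn4-1.

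**Figure D2:**
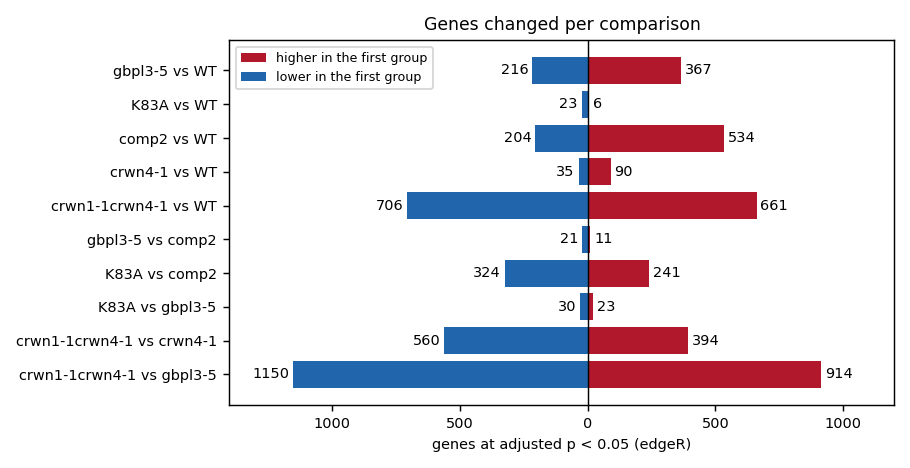
Number of genes called changed (edgeR, adjusted p under 0.05) in each of the 10 comparisons; bars to the right count genes higher and bars to the left genes lower in the first group named. The largest count is 1150 lower and 914 higher in crwn1-1crwn4-1 against gbpl3-5, and the smallest is 6 higher and 23 lower in K83A against WT.

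The comparison of gbpl3-5 with WT asks which genes change in whole seedlings when GBPL3 is mutated. Of the class III peroxidase genes some rose and others fell. The peroxidase AT2G18150 rose from 0.889 ± 0.461 to 23.55 ± 4.34 CPM (26.2-fold), and the peroxidase AT4G36430 rose from 3.64 ± 2.03 to 55.4 ± 6.96 CPM (15.1-fold). The peroxidases AT3G01190 (log2 fold change -1.91, adjusted p = 0.000137) and AT2G39040 (-2.61, adjusted p = 0.0011), named here after their values were seen, were lower. The tandem lipid-transfer-like genes AT5G46890 and AT5G46900 fell from 89.2 ± 18.5 to 4.78 ± 3.22 CPM and from 96.6 ± 26.7 to 5.97 ± 3.06 CPM. The tonoplast aquaporin TIP2;3 fell from 33.2 ± 2.33 to 2.76 ± 1.24 CPM.

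In gbpl3-5, 583 genes changed against WT, 367 higher and 216 lower. Of these, 356 of the higher and 191 of the lower ones had 3 values clear of the 3 WT values and a mean of at least 5 CPM. Chance alone separates 10% of genes, but these genes were called on the same values, so their separation is no independent support. Genes named for the size of their change, here and in the other comparisons with WT and of K83A with comp2, had all 3 values above or all 3 below those of the other group. Among the raised genes were a further peroxidase, AT4G08780 (log2 fold change 4.30, SE 0.898, adjusted p = 0.0155), the dehydrin-family gene AT4G38410 (4.13), the glycine-rich protein gene AT5G61660 (3.28), the phosphotransmitter gene AHP4 (2.58) and FER1, which encodes the iron-storage protein ferritin (2.22, SE 0.34, adjusted p = 0.00215). The lowered genes included MRD1 (-5.12, SE 0.88, adjusted p = 0.00469), the xyloglucan-modifying enzyme gene XTH21 (-4.18), AIR1 (-4.04), the fatty acid desaturase family gene AT1G06120 (-3.81), and the lipid-transfer-like genes AT4G12510 (-3.42) and AT4G12545 (-3.23). Salmon's division of reads between near-identical tandem copies makes the single values of AT5G46890, AT5G46900, AT4G12510, AT4G12545 and AIR1 uncertain.

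Thalianol is a root triterpene made by enzymes whose genes lie side by side. Of 11 genes of triterpene clusters, 6 were lower in gbpl3-5 and 5 did not pass, and adjusted over the list alone 8 were lower and 1 higher. The median log2 fold change was -2.36 (camera adjusted p = 4.72e-06), with adjusted p = 0.47 with an estimated correlation. Thalianol synthase (THAS1) fell from 19.9 ± 4.90 to 2.13 ± 0.704 CPM, CYP705A5 from 36.9 ± 8.07 to 4.58 ± 2.14 CPM, AT5G47980 from 8.08 ± 1.02 to 1.61 ± 0.188 CPM, and CYP71A16 of another cluster had a log2 fold change of -2.74 (SE 0.612, adjusted p = 0.021). Of 15 genes of the root endodermis and suberin, 5 were lower (7 adjusted over the list alone), with a camera adjusted p of 0.0011 and adjusted p = 0.621 with an estimated correlation. CASP1, CASP2 and CASP5, which encode proteins that position the Casparian strip, were lower by log2 fold changes of -1.35, -1.50 and -2.42. The root hair list had a median of -0.67 with 0 of 15 members called by edgeR or DESeq2 and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.000414, and adjusted p = 0.621 with an estimated correlation). The 38 genes of the root hair, root meristem and root endodermis lists had medians of -0.46 in gbpl3-5 and -0.50 in K83A. Their camera p was 0.109 and 0.0782 with an estimated correlation. For root genes in these lines, a smaller share of root tissue and lower expression within roots cannot be told apart.

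Of 37 photosynthesis genes, which mark green shoot tissue, 12 were higher in gbpl3-5 and 25 did not pass, and 34 were higher adjusted over the list alone. Their median was 0.73 (camera adjusted p = 9.15e-21, and adjusted p = 0.47 with an estimated correlation). PSAO rose from 1037 ± 139.8 to 2404 ± 956.1 CPM and PSBQ-2 from 606.4 ± 49.7 to 1119 ± 261 CPM, and PSAN (1.01) and PSBO2 (0.79) rose as well. Members of the LHCB1 and RBCS families share reads with near-identical copies and are uncertain. The mitosis list was lower (median -0.27, 1 of 23 called, PLE at -0.78; 6 adjusted over the list alone; camera adjusted p = 0.000943, and adjusted p = 0.47 with an estimated correlation). The nuclear lamina and envelope list was called lower (camera adjusted p = 0.0058, and adjusted p = 0.621 with an estimated correlation), with GBPL3 itself the 1 member called, also adjusted over the list alone. Single called members of lists that were not called were ALD1 of the salicylic acid list, whose 3 gbpl3-5 libraries held 0 reads against 0.522 ± 0.307 CPM in WT, and F3H of the flavonoid list (-0.77). Pericentromeric genes had 32 higher and 17 lower of 1666 (37 and 21 adjusted over the list alone), a median of 0.02 and a camera adjusted p of 0.86. Transposable element genes had 0 of 46 called by edgeR or DESeq2, 2 at an unadjusted p under 0.05, and a camera adjusted p of 0.27.

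The count of 583 rested on single libraries. It was 293 without WT replicate 2, 119 without WT replicate 3, 2050 without gbpl3-5 replicate 1, 294 without gbpl3-5 replicate 2, 186 without gbpl3-5 replicate 3, and 234 without both gbpl3-5 replicate 3 and comp2 replicate 2; a fit of the 2 groups alone called 57, with 18 higher and 39 lower, and DESeq2 called 1407.

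The line comp2 asks whether the genomic transgene restores expression in the mutant background. The 2 peroxidases were not raised in comp2, at 3.75 ± 1.19 CPM for AT4G36430 and 0.436 ± 0.409 CPM for AT2G18150. FUM2, a fumarase, rose from 2.06 ± 1.72 to 19.0 ± 3.01 CPM, and FBA5, an aldolase, from 123 ± 84.9 to 671.2 ± 66.2 CPM. The flavonoid genes DFR and LDOX fell from 10.9 ± 6.42 to 0.883 ± 0.796 CPM and from 9.66 ± 4.09 to 1.27 ± 1.01 CPM.

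In comp2, 738 genes changed against WT, 534 higher and 204 lower, of which 504 and 189 were separated from WT with a mean of at least 5 CPM. Raised genes included the thionin AT1G66100 (log2 fold change 4.69, SE 0.895, adjusted p = 0.00742), AT5G61660 (3.203), the gibberellin-regulated gene AT1G22690 (2.77), NUDT8 (2.72), AT1G64370 (2.68), the receptor kinase gene RK2 (2.63, SE 0.415, adjusted p = 0.00242), SCPL13 (2.60) and AT5G24155 (2.42). Lowered genes included AT2G47780, of the rubber elongation factor family (-4.96, SE 0.846, adjusted p = 0.00372), the efflux transporter AT2G04050 (-3.30), AT5G44440 (-2.65), MLS (-2.58), NAC044 (-2.40), LTP2 (-2.34) and AT5G13210 (-2.30).

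Of 37 photosynthesis genes, 20 were higher in comp2 (35 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 6.91e-27, and adjusted p = 0.274 with an estimated correlation). LHCA1 rose from 1840 ± 278.2 to 4697 ± 854 CPM, and PSBQ-2 (1.14), PSBO2 (0.94) and PSAD-2 (0.90) rose. Of 23 mitosis genes, 6 were lower (14 adjusted over the list alone), among them CDKB1;1 (-0.90), CDKB2;1 (-0.88), EDE1 (-1.23) and PLE (-0.99), with a camera adjusted p of 3.16e-09 and adjusted p = 0.106 with an estimated correlation. DNA replication genes were called as a list (camera adjusted p = 0.0177, and adjusted p = 0.427 with an estimated correlation) with 0 members called by edgeR or DESeq2 and 2 at an unadjusted p under 0.05. Of 19 flavonoid genes, 3 were lower (9 adjusted over the list alone), namely DFR, LDOX and UF3GT (-3.56), with a camera adjusted p of 0.000139 and adjusted p = 0.386 with an estimated correlation. The lists for salicylic acid (adjusted p = 0.4 with an estimated correlation), DNA damage (0.274), nuclear lamina (0.687) and triterpene clusters (0.551) were called lower by camera at adjusted p of 0.0177, 0.0177, 0.0387 and 0.0177, with 0, 1, 0 and 0 members called by edgeR, 1, 2, 0 and 3 by DESeq2 and 4, 5, 4 and 6 at an unadjusted p under 0.05 (0, 3, 0 and 3 lower adjusted over the list alone). Seed maturation genes had a median of 4.45 with 1 of 10 called and 6 adjusted over the list alone. The called member, the storage protein gene CRA1, averaged 64.5 ± 111.5 CPM, and the abscisic acid marker RAB18 averaged 21.1 ± 34.4 CPM. Both means were carried by comp2 replicate 2, the library with 269.7 CPM of seed maturation transcripts, and the list was not called (camera adjusted p = 0.493). The other lists with single called members were jasmonate (JAZ1, -1.53), root meristem (SCR, -0.67) and root endodermis (CASP5, -1.38).

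The count of 738 was 261 without WT replicate 2, 213 without WT replicate 3, 447 without comp2 replicate 1, 424 without comp2 replicate 3, and 819 without gbpl3-5 replicate 3 and comp2 replicate 2. A fit of the 2 groups alone called 182 genes, and DESeq2 called 1492, of which 62.3% were higher against 72.4% in edgeR.

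Set directly against comp2, gbpl3-5 had few called genes, which were led by those named above. The low count is not a measure of likeness to comp2, since another split of the libraries of these groups called 4466 genes. AT2G18150 was higher in gbpl3-5 by a log2 fold change of 5.75 (adjusted p = 0.000123) and AT4G36430 by 3.89 (adjusted p = 3.07e-05). GBPL3 itself (-2.33), AT5G46890 (-3.38), AT5G46900 (-3.13), TIP2;3 (-2.69), AT3G01190 (-1.31), XTH21 (-3.76) and AIR1 (-3.29) were lower. There were 32 such genes, 11 higher and 21 lower, of which 23 also changed in gbpl3-5 against WT in the same direction. These 23 were 3 of the higher and 20 of the lower genes. The listed gene NAC044 (2.27) was higher but was not called between gbpl3-5 and WT (log2 fold change -0.13). It was called lower in comp2 than in WT (-2.40), so its difference goes with a departure of comp2 from WT. Of 583 genes changed in gbpl3-5 against WT, 311 were also called in comp2 against WT in the same direction (270 higher and 41 lower). The median of the raised genes was 0.98 in gbpl3-5, 0.98 in comp2 and 0.35 in K83A, and the median of the lowered genes was -1.35, -0.68 and -0.77. These genes were chosen on gbpl3-5 against WT, and all of these medians use the same WT libraries. Part of each shared direction may therefore come from that choice. The direct comparison called 9 lists, none of them with an estimated correlation. They include triterpene clusters, lower in gbpl3-5 (median -0.94, 0 members called by edgeR, 2 by DESeq2, 7 at an unadjusted p under 0.05 and 3 adjusted over the list alone; camera adjusted p = 0.000483, and adjusted p = 0.35 with an estimated correlation), and copper homeostasis (median -0.38, 0 of 9 called by edgeR or DESeq2 and 2 at an unadjusted p under 0.05; camera adjusted p = 0.003, and adjusted p = 0.149 with an estimated correlation). The count of 32 was 56 without gbpl3-5 replicate 1 and 54 without comp2 replicate 2, and 39 without both gbpl3-5 replicate 3 and comp2 replicate 2. DESeq2 called 127 genes, 45.7% of them higher against 34.4% in edgeR, and a fit of the 2 groups alone called 1.

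**Figure D3:**
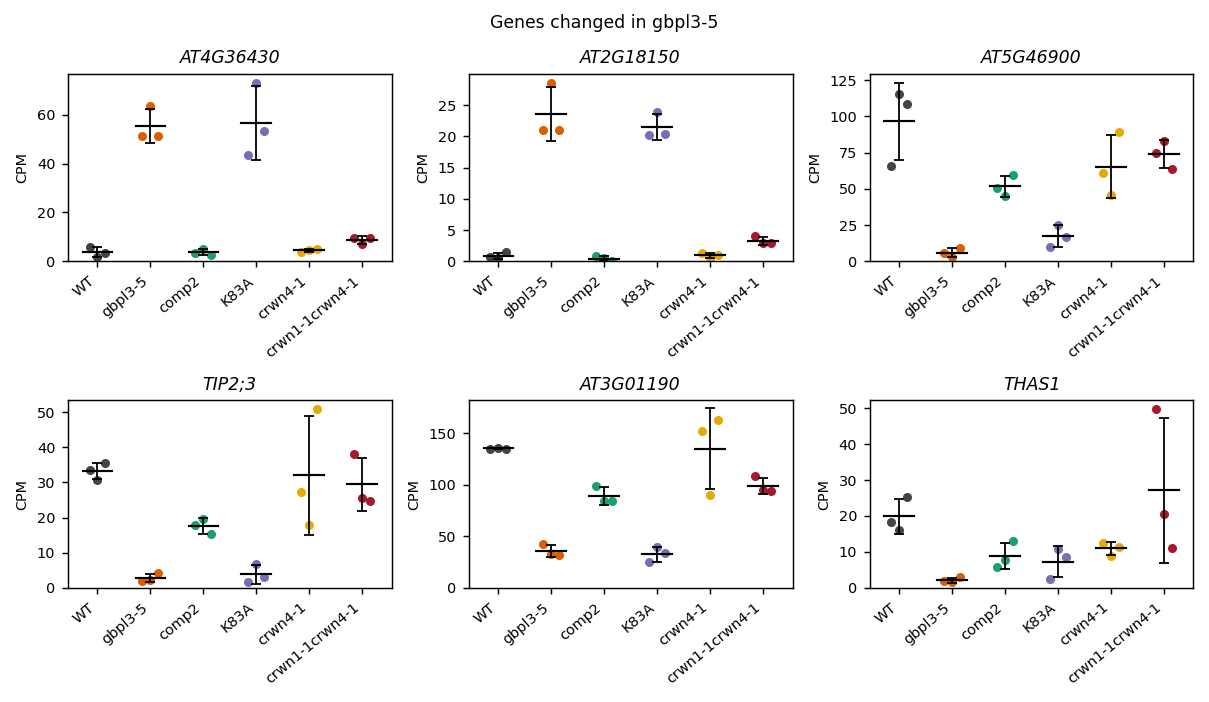
CPM of 6 genes that changed in gbpl3-5 against WT, in each of the 18 libraries; points are libraries, lines are group means and bars are SD (n = 3). AT4G36430 averaged 55.4 CPM in gbpl3-5 and 56.7 CPM in K83A against 3.64 in WT, and TIP2;3 averaged 2.76 and 3.82 against 33.2.

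The K83A line asks whether GBPL3 with an altered residue in its GTPase domain restores expression. The genes that changed most against WT included those named for gbpl3-5. AT4G36430 had 56.7 ± 15.03 CPM and AT2G18150 had 21.5 ± 2.06 CPM, and MRD1 (0.723 ± 0.668 CPM against 38.9 ± 3.91 in WT), TIP2;3 (3.82 ± 2.65 CPM), AT5G46890 (13.7 ± 6.74 CPM) and AT5G46900 (17.2 ± 7.73 CPM) were lower. The peroxidase AT3G01190 fell from 135.3 ± 0.749 to 32.7 ± 7.26 CPM.

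In K83A, 29 genes changed against WT, 6 higher and 23 lower, and 25 of them also changed in gbpl3-5 in the same direction. The raised genes held the epithiospecifier modifier ESM1 (log2 fold change 1.58, SE 0.215, adjusted p = 0.00372). Lowered genes included AT4G33120 (-2.11), AT4G22460 (-2.08), the iron-uptake regulator FRU (-1.86, SE 0.326, adjusted p = 0.0209) and the copper/zinc superoxide dismutase CSD1 (-1.83, SE 0.31, adjusted p = 0.0175). The low count alone is not a measure of likeness to WT, since 1573 genes had an unadjusted p under 0.05 and DESeq2 called 184. Part of the 1573 would arise by chance. Both counts were the lowest of the comparisons with WT, the others having 2508 to 4147 unadjusted and 637 to 2116 by DESeq2.

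Of 9 copper homeostasis genes, 1 was lower in K83A (4 adjusted over the list alone), with a median of -1.11 (camera adjusted p = 3.82e-05, and adjusted p = 0.0233 with an estimated correlation). A further 11 lists were called by camera at lower or higher levels but not with an estimated correlation. Photosynthesis was higher (median 0.47, 0 of 37 called by edgeR or DESeq2 and 18 at an unadjusted p under 0.05; camera adjusted p = 1.48e-19, and adjusted p = 0.207 with an estimated correlation). Heat shock was higher (median 0.65, 0 of 17 called by edgeR or DESeq2 and 2 at an unadjusted p under 0.05; 0.000171, and adjusted p = 0.1 with an estimated correlation). The stomatal lineage was higher as a list alone (median 0.29, 0 of 10 called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05; 0.0203, and adjusted p = 0.149 with an estimated correlation). Lower lists were the iron deficiency response (median -0.77, 1 of 17 called and 7 adjusted over the list alone; 5.07e-05), triterpene clusters (median -0.91, 0 of 11 called by edgeR, 3 by DESeq2 and 6 at an unadjusted p under 0.05, 4 lower and 1 higher adjusted over the list alone; 5.07e-05), root hair (median -0.56, 0 of 15 called by edgeR or DESeq2 and 6 at an unadjusted p under 0.05; 1.35e-06) and root endodermis (median -0.49, 0 of 15 called by edgeR, 2 by DESeq2, 4 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone; 0.000106), each with adjusted p = 0.207 with an estimated correlation. Salicylic acid and defence (median -0.55, 0 of 27 called by edgeR, 1 by DESeq2, 6 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone; 2.06e-05) and DNA damage (median -0.23, 0 of 18 called by edgeR or DESeq2 and 2 at an unadjusted p under 0.05; 0.00623) were lower, each with adjusted p = 0.119 with an estimated correlation. The abscisic acid and cold response (median -0.50, 0 of 16 called by edgeR, 2 by DESeq2, 3 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone; 0.00452, and adjusted p = 0.433 with an estimated correlation) was lower. Flavonoids (median -0.38, 1 of 19 called, F3H at -1.04, and 2 adjusted over the list alone; 0.0014, and adjusted p = 0.344 with an estimated correlation) were lower as well. The count of 29 was 15 without WT replicate 3, 6 without K83A replicate 1, 16 without K83A replicate 3, and 38 without gbpl3-5 replicate 3 and comp2 replicate 2.

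K83A against comp2 sets 2 transgenes that differ by the K83A substitution side by side. Each transgene was measured as 1 group, so the substitution cannot be told apart from other differences between the lines. Of the peroxidase genes, AT2G18150 (21.5 against 0.436 CPM), AT4G36430 (56.7 against 3.75 CPM) and PRX52 (10.2 against 0.683 CPM) were higher in K83A, and AT3G01190 (32.7 against 89.0 CPM, adjusted p = 0.00239) was lower. The copper homeostasis genes CSD1, CCS and CSD2 were lower, with CSD1 at 17.7 ± 2.704 against 52.5 ± 9.54 CPM, the chaperone CCS at 5.77 ± 1.14 against 18.3 ± 2.78 CPM and CSD2 at 17.1 ± 1.117 against 47.2 ± 16.5 CPM.

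The 2 lines differed in 565 genes, 241 higher and 324 lower in K83A. Higher genes included AT2G47780 (log2 fold change 4.07), AT5G44440 (2.90), LTP2 (2.55), HEC1 (2.55, SE 0.315, adjusted p = 0.000853), MLS (2.52), AT1G33790 (2.35) and CXE13 (2.35). Lower genes included AT1G66100 (-4.35), FUM2 (-3.37), RK2 (-3.27, SE 0.433, adjusted p = 0.00138), NUDT8 (-2.82), AT5G23240 (-2.70), AT5G52790 (-2.67), MIOX1 (-2.44) and CRK18 (-2.28). Of these genes, AT2G47780, AT5G44440, LTP2 and MLS were called lower in comp2 than in WT. AT1G66100, FUM2, RK2 and NUDT8 were called higher in comp2 than in WT. Their difference between the 2 lines thus goes with a departure of comp2 from WT. Of 9 copper homeostasis genes, 3 were lower (7 adjusted over the list alone), with a median of -1.47 (camera adjusted p = 8.92e-06, and adjusted p = 0.0119 with an estimated correlation). Of 23 mitosis genes, 6 were higher (14 adjusted over the list alone), such as CDKB2;1 (0.88), EDE1 (1.31) and HIK (0.82), with a camera adjusted p of 5.88e-09 and adjusted p = 0.0513 with an estimated correlation. In K83A against WT, edgeR and DESeq2 called 0 of these 23, and 0 had an unadjusted p under 0.05. In comp2 against WT edgeR called 6, all lower, so the mitosis difference also goes with a departure of comp2 from WT. The abscisic acid and cold list had 4 of 16 lower, COR47 (-1.07), ERD10 (-0.86), COR15B (-3.03) and RAB18 (-6.56) (5 adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.672 with an estimated correlation). RAB18 followed comp2 replicate 2, and the COR15B values of the 2 groups overlapped. FRU was lower (-1.91), and the iron transporter gene OPT3 (1.02), the auxin gene GH3.3 (2.33), SCR (0.84), TMM (0.87), NAC044 (1.58) and UF3GT (3.64) were higher. BIP3 (-5.21) and PSBO2 (-0.66) were lower. Among these, SCR, NAC044 and UF3GT were called lower, and PSBO2 higher, in comp2 than in WT. CRA1 (-8.69) was called lower through comp2 replicate 2 alone, with 0.4061, 193.2 and 0 CPM in comp2 against 0 to 0.2888 CPM in K83A. The count of 565 was 290 without comp2 replicate 1, 241 without comp2 replicate 3, 142, 73 and 327 without K83A replicates 1, 2 and 3, and 676 without gbpl3-5 replicate 3 and comp2 replicate 2. A fit of the 2 groups alone called 150, and DESeq2 called 1380.

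Directly against gbpl3-5, K83A differed in 53 genes, 23 higher and 30 lower, with GBPL3 itself higher by a log2 fold change of 2.71 (adjusted p = 0.00163). The peroxidases AT4G36430 (0.03) and AT2G18150 (-0.13) were not called, while AT1G06120 (2.36, adjusted p = 0.0263), AT4G12510 (1.91, adjusted p = 0.0263) and the aquaporin gene PIP2;4 (1.33, adjusted p = 0.0353; chosen after its values were seen) were higher in K83A than in gbpl3-5. Triterpene genes had a median of 1.60 with 0 of 11 called by edgeR, 4 by DESeq2, 6 at an unadjusted p under 0.05 and 6 higher adjusted over the list alone (camera adjusted p = 0.00357, and adjusted p = 0.505 with an estimated correlation). The count of 53 was 828, 7 and 6 without gbpl3-5 replicates 1, 2 and 3, 3 without K83A replicate 1, 3 without K83A replicate 2, 20 without K83A replicate 3, and 7 without gbpl3-5 replicate 3 and comp2 replicate 2. A fit of the 2 groups alone called 5, and DESeq2 called 547. Of the calls 43.4% were higher, against 53.2% with the transcript length offset, 51.7% with limma-trend on the deposited values and 36.6% with DESeq2. Which direction prevailed thus depended on the processing.

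The crwn4-1 mutant asks for the effect of losing CRWN4 alone. FUM2, FBA5 and RK2, which were called higher in comp2, were called higher here too. FUM2 rose from 2.06 ± 1.72 to 10.3 ± 2.42 CPM, FBA5 from 123 ± 84.9 to 541.8 ± 45.9 CPM and RK2 from 2.49 ± 1.89 to 13.7 ± 0.566 CPM. MRD1 fell from 38.9 ± 3.91 to 0.167 ± 0.258 CPM. It stood at 1.05 ± 1.66 CPM in gbpl3-5, 0.723 ± 0.668 CPM in K83A, 6.65 ± 2.04 CPM in comp2 and 48.3 ± 4.1 CPM in crwn1-1crwn4-1. The gene AT1G75945 had 101, 283 and 105 reads in the crwn4-1 libraries, 97, 148 and 104 reads in crwn1-1crwn4-1, 0, 0 and 1 read in WT and at most 4 reads in each of the other 9 libraries.

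In crwn4-1, 125 genes changed against WT, 90 higher and 35 lower, and 124 of these were separated from WT with a mean of at least 5 CPM. Raised genes included NUDT8 (log2 fold change 2.33), AT1G22690 (2.32, SE 0.368, adjusted p = 0.00863), CYP71B4 (2.12), AT4G05070 (2.11) and FRO6, a ferric reductase of green tissue (1.903). Lowered genes included CRWN4 itself (-2.85, SE 0.302, adjusted p = 0.000431), AT2G47780 (-3.70), AT1G80130 (-2.58), LTP2 (-2.33), AT5G13210 (-2.16), AT5G44440 (-2.08), SUFE2 (-1.99), CYP707A2, an enzyme of abscisic acid breakdown (-1.92), and GSTF6 (-1.904).

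Of 37 photosynthesis genes, 0 were called in crwn4-1 by edgeR, 7 by DESeq2 and 27 at an unadjusted p under 0.05, and 20 were higher adjusted over the list alone (median 0.56; camera adjusted p = 4.27e-19, and adjusted p = 0.26 with an estimated correlation). Mitosis genes were lower (median -0.40, 1 of 23 called, PLE at -0.84, also 1 adjusted over the list alone; camera adjusted p = 2.94e-08, and adjusted p = 0.156 with an estimated correlation). Flavonoid genes had 0 of 19 called by edgeR, 4 by DESeq2, 9 at an unadjusted p under 0.05 and 7 lower adjusted over the list alone (median -0.51; 8.65e-07, and adjusted p = 0.247 with an estimated correlation). The iron deficiency list was higher (median 0.61, 0 called by edgeR or DESeq2 and 3 at an unadjusted p under 0.05; 8.12e-05) and DNA replication lower (median -0.22, 0 called by edgeR or DESeq2 and 0 at an unadjusted p under 0.05; 0.00351), each with adjusted p = 0.26 with an estimated correlation. A further 6 lists were called by camera: nuclear lamina lower (0.0193, and adjusted p = 0.553 with an estimated correlation), copper higher (0.0438, and adjusted p = 0.247 with an estimated correlation), root hair higher (0.0432, and adjusted p = 0.772 with an estimated correlation), DNA damage lower and stomatal lineage lower (0.0432 each, and adjusted p = 0.247 with an estimated correlation), and transposable element genes lower (median -0.11, 0 of 46 called by edgeR, 1 by DESeq2 and 3 at an unadjusted p under 0.05; 0.0432, and adjusted p = 0.504 with an estimated correlation). Of the copper, root hair, DNA damage and stomatal lists edgeR called 0 members, DESeq2 0, 0, 2 and 2, and 2, 1, 2 and 5 had an unadjusted p under 0.05. Of the 44 nuclear lamina genes edgeR called 1, the targeted gene CRWN4 itself, and 2 had an unadjusted p under 0.05. The count of 125 was 240, 5 and 11 without WT replicates 1, 2 and 3, 66, 24 and 82 without crwn4-1 replicates 1, 2 and 3, and 274 without gbpl3-5 replicate 3 and comp2 replicate 2. DESeq2 called 637, a fit of the 2 groups alone called 58, and after removal of length and GC trends 387 were called, of which 53.5% were higher against 72% before. After that removal camera called fewer lists, 5 against 11 before.

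The crwn1-1crwn4-1 double mutant asks for the effect of losing both CRWN proteins. Of 40 genes that plants raise when oxygen is short, a list chosen after the data had been seen, 23 were called higher by edgeR, and the 33 of them that had not already been seen among the most changed genes had a median log2 fold change of 1.38 with 16 called higher (camera p = 5.33e-19, and p = 0.000603 with an estimated correlation, neither adjusted). Alcohol dehydrogenase (ADH1) rose from 6.49 ± 3.04 to 105 ± 8.60 CPM, the hemoglobin HB1 from 4.67 ± 2.01 to 99.9 ± 33.8 CPM, the desaturase FTM1 from 4.37 ± 1.96 to 151.9 ± 18.6 CPM, and AT5G15120, a putative cysteine-type thiol dioxygenase, from 2.42 ± 0.612 to 40.6 ± 11.2 CPM. CIPK20 fell from 21.4 ± 6.47 to 1.61 ± 0.595 CPM and LHCB2.3 from 93.7 ± 29.8 to 10.2 ± 2.703 CPM.

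In crwn1-1crwn4-1, 1367 genes changed against WT, 661 higher and 706 lower, and 608 and 660 of them were separated from WT with a mean of at least 5 CPM. Further raised genes were AT2G17850 (log2 fold change 5.94), AT4G27450 (4.80, SE 0.561, adjusted p = 6.41e-05), RTFL12 (4.51), AT1G33055 (4.38) and AT4G12735 (3.89). Further lowered genes were CRWN1 (-3.43, SE 0.234, adjusted p = 1.91e-07), CRWN4 (-3.35, SE 0.309, adjusted p = 6.78e-06), AT5G06980 (-3.76), AT1G13650 (-3.57), CYP79F1 of aliphatic glucosinolate synthesis (-2.99), AT3G44450 (-2.98), the auxin-responsive GH3 gene DFL2 (-2.94) and AT3G55240 (-2.85).

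Of 17 heat shock genes, 7 were higher in crwn1-1crwn4-1 and 10 did not pass (10 higher adjusted over the list alone), with a median of 1.58 (camera adjusted p = 8.88e-10, and adjusted p = 0.00593 with an estimated correlation). HSP23.6-MITO rose from 0.354 ± 0.350 to 7.05 ± 1.105 CPM, MBF1C from 5.95 ± 1.65 to 27.2 ± 5.52 CPM, HSP70 from 37.1 ± 5.84 to 129.7 ± 39.8 CPM, and HSP101 from 8.99 ± 2.12 to 19.9 ± 4.91 CPM. Of 23 mitosis genes, 11 were lower (19 adjusted over the list alone), among them PLE (-1.09), CYCA1;1 (-1.14), HIK (-0.94) and TPX2 (-0.99), with a median of -0.70 (camera adjusted p = 1.13e-13, and adjusted p = 0.0124 with an estimated correlation). Of 15 DNA replication genes, 4 were lower (10 adjusted over the list alone), namely PRL (-0.85), PCNA1 (-0.67), RNR1 (-0.83) and MCM3 (-0.84), with a camera adjusted p of 2.18e-06 and adjusted p = 0.118 with an estimated correlation. Flavonoid genes went both ways, with F3H (-1.31) and FLS1 (-0.85) lower and the regulator MYB111 (1.19) higher (1 higher and 4 lower adjusted over the list alone; median -0.88; camera adjusted p = 4.05e-05, and adjusted p = 0.428 with an estimated correlation).

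Of 37 photosynthesis genes, 4 light-harvesting genes were lower (5 adjusted over the list alone): LHCB2.1 (-2.62), LHCB2.2 (-2.55), LHCB3 (-1.21) and CAB2 (-1.30), of which LHCB2.1, LHCB2.2 and CAB2 have near-identical copies and are uncertain singly. The list as a whole had a median of -0.08 and was not called (camera adjusted p = 0.0504). The root hair list was called lower with 0 members called by edgeR or DESeq2 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.0441, and adjusted p = 0.788 with an estimated correlation). In the nuclear lamina list, AT1G59660 rose from 7.07 ± 2.65 to 34.5 ± 4.51 CPM, and CRWN1, CRWN4 and AT1G54385 (6.598 against 13.2 CPM) were lower, the same 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.212). Other called members were ACD6 (1.68), CBF2 (4.15, with replicate 2 at 0.712 CPM, among the WT values) and the superoxide dismutase chaperone CCS (1.26), which were higher, and JAZ10 (-1.46), DOG1 (-2.63) and SCRM2 (-0.88), which were lower. Pericentromeric genes had 50 higher and 58 lower of 1666 (50 and 57 adjusted over the list alone; camera adjusted p = 0.778). Of 46 transposable element genes, 1 was lower, 0 adjusted over the list alone (camera adjusted p = 0.485). The count of 1367 was 618 without WT replicate 2, 741 without WT replicate 3, 638, 694 and 527 without crwn1-1crwn4-1 replicates 1, 2 and 3, and 1731 without gbpl3-5 replicate 3 and comp2 replicate 2. DESeq2 called 2116, and a fit of the 2 groups alone called 2679.

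**Figure D4:**
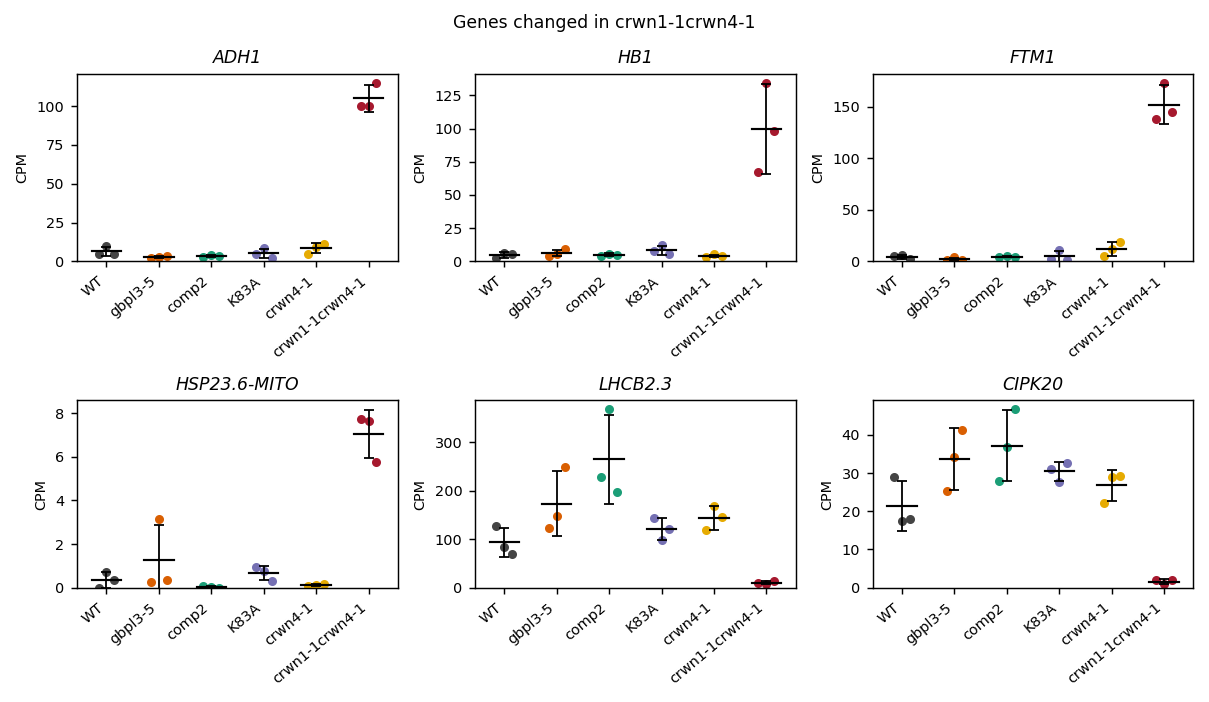
CPM of 6 genes that changed in crwn1-1crwn4-1 against WT, in each of the 18 libraries; points are libraries, lines are group means and bars are SD (n = 3). ADH1 averaged 105 CPM in crwn1-1crwn4-1 against 6.49 in WT, and CIPK20 averaged 1.61 against 21.4.

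The comparison of crwn1-1crwn4-1 with crwn4-1 asks what the loss of CRWN1 adds to that of CRWN4. No crwn1-1 mutant alone was measured, and each genotype was a single group. The loss of CRWN1 therefore cannot be told apart from other differences between the lines. The heat shock genes HSP23.6-MITO (7.05 ± 1.105 against 0.12 ± 0.0541 CPM) and HSP70 (129.7 ± 39.8 against 37.6 ± 18.19 CPM) were higher in the double mutant. The photosynthesis genes LHCB3 (969.8 ± 262.7 against 3177 ± 619.1 CPM) and LHCA4 (1536 ± 416.3 against 3895 ± 533.7 CPM) were lower. The 2 mutants differed in 954 genes, 394 higher and 560 lower in the double mutant. Heat shock had 3 of 17 higher (8 adjusted over the list alone; camera adjusted p = 2.25e-09, and adjusted p = 0.00667 with an estimated correlation). Photosynthesis had 15 of 37 lower (26 adjusted over the list alone; camera adjusted p = 8.05e-22, and adjusted p = 0.42 with an estimated correlation). The ferric and cupric reductase genes FRO4 (-2.35) and FRO5 (-2.97), the jasmonate synthesis gene AOS (-1.56), TIFY7 (-1.01), PRP1 (-1.37) and DOG1 (-3.01) were lower, and NAC044 (2.07), GMI1 (1.69), CSD2 (1.46), CBF2 (3.23, but not in crwn1-1crwn4-1 replicate 2), CYP708A2 (2.15) and MYB111 (1.59) were higher. The count of 954 was 508 without crwn4-1 replicate 1, 622 without crwn4-1 replicate 2, 488, 468 and 467 without crwn1-1crwn4-1 replicates 1, 2 and 3, and 1172 without gbpl3-5 replicate 3 and comp2 replicate 2. DESeq2 called 1548.

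The direct comparison of crwn1-1crwn4-1 with gbpl3-5 tests the difference between the mutants of these lamina components. The triterpene gene THAS1 was higher in crwn1-1crwn4-1 (log2 fold change 3.69), as were the endodermis gene CASP2 (17.9 ± 3.18 against 5.63 ± 1.497 CPM) and the heat shock gene HSP90.1 (50.4 ± 10.2 against 16.3 ± 1.59 CPM). The photosynthesis gene LHCB3 was lower (969.8 ± 262.7 against 3473 ± 1174 CPM). In all 2064 genes differed, 914 higher and 1150 lower. Triterpene genes had 6 of 11 higher (9 adjusted over the list alone; camera adjusted p = 1.37e-05), endodermis genes 6 of 15 higher (9 adjusted over the list alone; 1.74e-05) and photosynthesis genes 26 of 37 lower (33 adjusted over the list alone; 2.32e-22), each with adjusted p = 0.2 with an estimated correlation. Heat shock genes had 6 of 17 higher (9 adjusted over the list alone; 5.34e-08, and adjusted p = 0.015 with an estimated correlation). Jasmonate genes went both ways, with 3 of 21 higher, MYC2 (3.03), JAZ1 (1.38) and CYP94B3 (2.08), and 5 lower, AOS (-1.33) among them, the same counts adjusted over the list alone. In the 3 higher genes crwn1-1crwn4-1 replicate 2 lay below the highest gbpl3-5 value. CSD1 (1.58), CSD2 (1.57) and CCS (1.18) were higher, and FLC (-1.57), DOG1 (-3.08), SCRM2 (-1.15) and BASL (-1.23) were lower. The count of 2064 was 1235 without gbpl3-5 replicate 2, 976, 1188 and 1116 without crwn1-1crwn4-1 replicates 1, 2 and 3, and 1775 without gbpl3-5 replicate 3 and comp2 replicate 2. With a minimum absolute log2 fold change of 1 it was 1074.

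Comparisons against WT share its 3 libraries. Simulated unchanged groups gave a correlation of log2 fold changes across genes, which are not independent replicates, of 0.499 and a covariance of 0.109 (highest 0.116). They gave at most 0 shared calls. With no gene changed, few or no genes are called at all, so this count is no reference for the real ones. The simulation drew genes independently, so its covariances leave out genes that vary together. Genes of gbpl3-5 and comp2 had the most shared calls, with 270 higher and 41 lower in both against 9.46 and 2.13 for independent lists, a correlation of 0.595 and a covariance of 0.32. For gbpl3-5 and K83A, 5 higher and 20 lower were shared (0.106 and 0.24 for independent lists; correlation 0.471, covariance 0.217). For gbpl3-5 and crwn4-1, 74 higher and 11 lower were shared (1.59 and 0.365; 0.535, covariance 0.237). For comp2 and crwn4-1 these were 83 and 23 (2.32 and 0.345; 0.665, covariance 0.29). In gbpl3-5 and crwn1-1crwn4-1, 67 genes were higher and 20 lower in both and 13 went opposite ways (12 and 7.36 for independent lists; correlation 0.317, covariance 0.172). In crwn4-1 and crwn1-1crwn4-1, 29 and 10 were shared and 2 opposite (2.87 and 1.19; 0.403, covariance 0.177). Shared between comp2 and K83A were 1 higher gene and 0 lower (0.155 and 0.227 for independent lists; 0.328, covariance 0.149). Between comp2 and crwn1-1crwn4-1 they were 80 and 59, with 16 opposite (17 and 6.95; 0.315, covariance 0.168). K83A shared 0 higher and 1 lower gene with crwn4-1 (0.0261 and 0.0389; 0.304), with a covariance of 0.114 that did not exceed the simulated highest, and 4 and 2 with crwn1-1crwn4-1 (0.191 and 0.784; 0.286, covariance 0.131). The correlation of comp2 with crwn4-1 was thus the highest. Only this one and those of gbpl3-5 with comp2 and with crwn4-1 exceeded the simulated 0.499, and the others lay below it. Libraries of the same number deviated together in gbpl3-5, crwn4-1 and crwn1-1crwn4-1 (9 of 9 pairs with a correlation over 0.1), which the simulation leaves out. The 3 WT libraries are too few to split, so part of each excess may come from the shared controls.

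**Figure D5:**
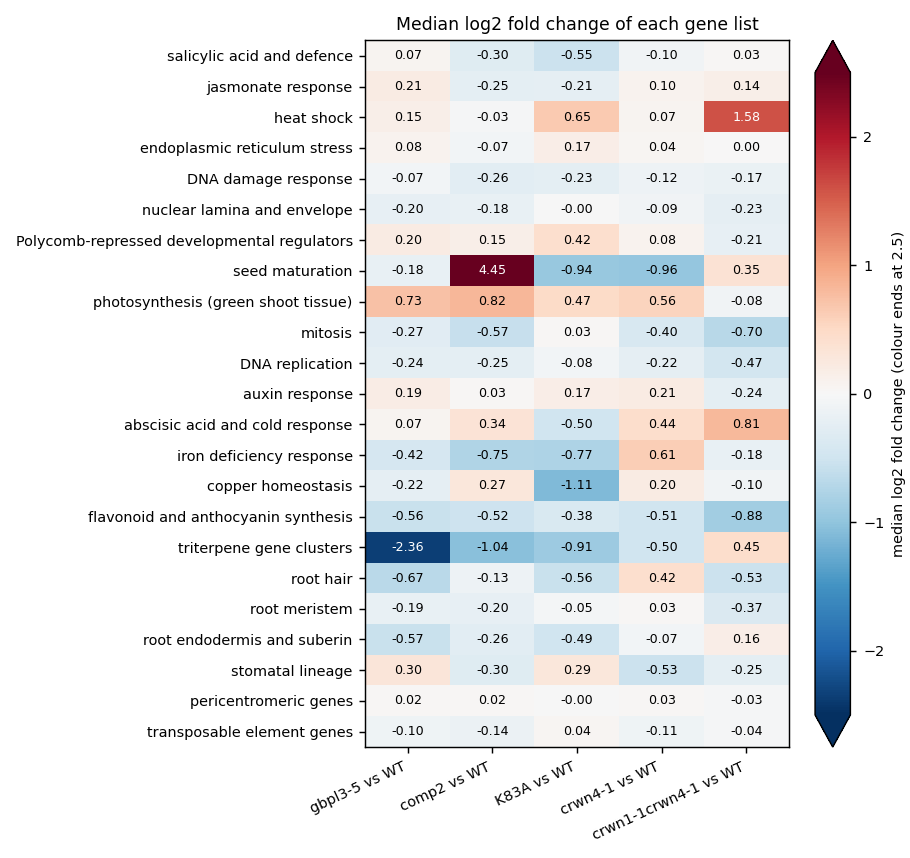
Median log2 fold change of each of the 23 gene lists in the 5 comparisons with WT; each cell gives the median over the list's tested genes, and colour runs from blue (lower than WT) to red (higher) and ends at 2.5. The lowest median is -2.36 for triterpene gene clusters in gbpl3-5, and the highest is 4.45 for seed maturation in comp2, which comp2 replicate 2 carried.

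The remaining lists are given here for the comparisons with WT. Camera's adjusted p for the endoplasmic reticulum stress list was between 0.445 and 0.94 in the 5 comparisons, for the auxin list between 0.222 and 0.94, and for the Polycomb list between 0.114 and 0.958, and DOG1 in crwn1-1crwn4-1 was the 1 member edgeR called in these 15 tests. DESeq2 called 2 endoplasmic reticulum stress, 2 Polycomb and 1 auxin member in comp2, and 2 Polycomb and 1 auxin member in crwn1-1crwn4-1. The root meristem list was not called in any of the 5 (lowest camera adjusted p 0.0936, in comp2). In several lists the median, the mean and the test differed in sign, among them salicylic acid in gbpl3-5 (median 0.07, mean -0.10), heat shock in crwn4-1 (median 0.07, mean -0.09), and jasmonate in crwn1-1crwn4-1 (median 0.14, camera lower, adjusted p = 0.531).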

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

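All tests that weigh explanations, the low oxygen and clock lists, the removal of length and GC trends, and the choice of these 3 list differences were made after the results they concern had been seen, and for the tests of root markers and of single libraries the outcome was known at least in part when they were chosen.

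A direct comparison of 2 groups showed a difference in 3 list tests that also passed with an estimated correlation between genes. Copper homeostasis genes were lower in K83A than in comp2 (adjusted p = 0.0119 with an estimated correlation, median log2 fold change -1.47, below 0 in 9 of 9 genes), with lower levels of the superoxide dismutases CSD1 and CSD2 and their chaperone CCS. Heat shock genes were higher in crwn1-1crwn4-1 than in crwn4-1 (adjusted p = 0.00667, median 1.26, above 0 in 17 of 17 genes). They were also higher in crwn1-1crwn4-1 than in gbpl3-5 (adjusted p = 0.015, median 1.395, above 0 in 16 of 17 genes). In each of these 2 comparisons 8 of 18 listed clock genes were called as well. The time of harvest, the handling of the plants and the genotype are thus all open for the heat shock genes.

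Genes that respond to low oxygen were higher in crwn1-1crwn4-1 than in WT. Of 40 listed genes 23 were called higher, and the 33 that had not already been seen among the most changed genes had a median log2 fold change of 1.38, with 16 called higher. Trends with transcript length and GC content are argued against as the whole cause, since the median was 1.23 after their removal, and so is a single library, since the lowest median with 1 of the 6 libraries left out was 1.38. A difference in clock phase or time of harvest stays open and may contribute: 9 of 18 listed clock genes were called (permutation p = 1e-04, the smallest these permutations can give), with 5 morning and 3 evening genes lower and 1 evening gene higher. The harvest time of each group is not in the sources used here, so the time of harvest, the handling of the plants and the genotype are all open.

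Camera called the photosynthesis list higher than in WT in gbpl3-5, comp2, K83A and crwn4-1, but not with an estimated correlation (adjusted p = 0.47, 0.274, 0.207 and 0.26), and of its 37 genes edgeR called 12, 20, 0 and 0, DESeq2 23, 29, 0 and 7, and 34, 35, 18 and 27 had an unadjusted p under 0.05. After the length and GC trends were removed the list median stayed at no less than 2/3 of its value in 4 of 4 comparisons, and with any one WT library left out it did so in 4 of 4, which argues against the trend and against one WT library as the whole cause. For a larger share of shoot tissue, 38 root marker genes had medians of -0.46 in gbpl3-5, -0.23 in comp2, -0.50 in K83A and 0.15 in crwn4-1 (p = 0.109, 0.413, 0.0782 and 0.872 with an estimated correlation), so that explanation and a change of expression within tissues cannot be told apart in any of the 4; these genes come from lists whose results had already been seen. A difference in age or growth stays open. The seed maturation list, meant to mark remains of the seed stage, was not called in any of these 4 groups against WT. That list cannot decide the question, since its genes summed to at most 9.07 CPM in each library other than comp2 replicate 2. MLS, a gene of stored lipid use, averaged 80.5 CPM in WT and 36.6, 13.4, 76.7 and 16.4 CPM in these 4 groups.

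More genes were called in comp2 against WT (738) than in gbpl3-5 against WT (583), although comp2 carries the transgene. Single libraries may set this order, since gbpl3-5 had more calls than comp2 in 2 of the 6 fits that left out 1 WT or gbpl3-5 library. These were the fits without WT replicate 2 (293 against 261) and without gbpl3-5 replicate 1 (2050 against 889). Without comp2 replicates 1, 2 and 3, gbpl3-5 had more calls as well (503 against 447, 660 against 633 and 642 against 424). Fits without a gbpl3-5 or a comp2 library leave that group with fewer samples and do not compare the 2 counts evenly. Whether comp2 replicate 3, which stood apart, has a part of its own cannot be told apart from the loss of a sample, since 424 genes were called in comp2 without it and 213 to 633 without another comp2 or WT library. The length and GC trend is argued against as the cause, since 1370 genes were called in comp2 and 980 in gbpl3-5 after its removal. Clock phase or time of harvest stays open. In comp2, 0 of 18 clock genes were called by edgeR, 3 by DESeq2 and 5 at an unadjusted p under 0.05 (permutation p = 1 for the edgeR count). The morning minus evening index differed from WT by -0.75 in comp2 (95% interval -1.10 to -0.39). In gbpl3-5 it differed from WT by -0.504 (-1.164 to 0.157) and in crwn4-1 by -0.716 (-1.537 to 0.105). Between gbpl3-5 and comp2 the index differed by 0.242 (-0.417 to 0.901), so a shift particular to comp2 was not shown. An effect of the transgene or of its insertion is untested.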

How the results depend on the processing

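The removal of length and GC trends and the joint omission of gbpl3-5 replicate 3 and comp2 replicate 2 were chosen after the data had been seen; the other alternatives were planned. Counts of changed genes are given in the order gbpl3-5, K83A, comp2, crwn4-1 and crwn1-1crwn4-1 against WT (583, 29, 738, 125 and 1367), gbpl3-5 and K83A against comp2 (32 and 565), K83A against gbpl3-5 (53), and crwn1-1crwn4-1 against crwn4-1 and gbpl3-5 (954 and 2064). RLE scaling, no filter, the transcript length offset and limma-trend on the deposited values left all 10 within 1.5 times. Of 285 named results, 283 kept their call with RLE scaling, 284 with DESeq2 and 274 with the length offset. A gene without a DESeq2 adjusted p was counted as kept. None of the called named results or of the 86 list calls changed direction where direction was compared. Direction was not compared for named results that were not called, nor in the mixed fry test, which gives no direction. The balance of calls turned between mostly higher and mostly lower in 6 comparisons. In gbpl3-5 against WT 367 of 583 were higher, but 18 of 57 in the fit of the 2 groups alone and 961 of 2050 without gbpl3-5 replicate 1. In K83A against WT 6 of 29 were higher, but 4 of 6 without K83A replicate 1. In crwn1-1crwn4-1 against WT 661 of 1367 were higher, but 645 of 1245 without the filter, 1383 of 2679 in the 2 groups alone and 376 of 694 without its replicate 2 (320 of 638 without its replicate 1). In gbpl3-5 against comp2 11 of 32 were higher, but 1 of 1 in the 2 groups alone, 20 of 39 without gbpl3-5 replicate 3 and comp2 replicate 2, and 30 of 54 without comp2 replicate 2. In K83A against gbpl3-5 23 of 53 were higher, but 25 of 47 with the length offset, 30 of 58 with limma-trend, 4 of 5 in the 2 groups alone, 507 of 828 without gbpl3-5 replicate 1 (3 of 6 without its replicate 3), and 2 of 3, 2 of 3 and 13 of 20 without K83A replicates 1, 2 and 3. In crwn1-1crwn4-1 against gbpl3-5 914 of 2064 were higher, but 1378 of 2635 without gbpl3-5 replicate 1. Depth limits genes under 1 CPM, such as ALD1. Where results changed below, the cause was not tested, except that fits of 2 groups or without a library use fewer samples.

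After removal of length and GC trends 980, 47, 1370 and 387 genes were called in the first 4 comparisons, 55 and 1083 against comp2 and 127 in K83A against gbpl3-5; of these 980, 523 had also been called without the removal. Genes shared with gbpl3-5 were 215 for crwn4-1 (85 before) and 173 for crwn1-1crwn4-1 (87 before), and 142 (39 before) were shared by crwn4-1 and crwn1-1crwn4-1. Of the genes changed in gbpl3-5, 41 (23 before) were called against comp2 and 563 (311 before) in comp2 against WT, and 5 (11 before) lists were called in crwn4-1.

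DESeq2 called 1407, 184, 1492, 637 and 2116 genes against WT, 127 and 1380 against comp2, 547 in K83A against gbpl3-5 and 1548 in crwn1-1crwn4-1 against crwn4-1. It shared 102, 353 and 244 genes between gbpl3-5 and K83A, crwn4-1 and crwn1-1crwn4-1 (25, 85 and 87 in edgeR), 9 and 25 between K83A and crwn4-1 and crwn1-1crwn4-1 (1 and 6), and 217 between these mutants (39). Of its genes changed in gbpl3-5, 80 were called against comp2, 716 in comp2 against WT and 102 in K83A against WT (23, 311 and 25 in edgeR).

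Fits of the 2 groups alone called 57 genes in gbpl3-5, 182 in comp2, 58 in crwn4-1 and 2679 in crwn1-1crwn4-1 against WT, 1 and 150 against comp2, and 5 in K83A against gbpl3-5. Without gbpl3-5 replicate 3 and comp2 replicate 2 together, 234 genes were called in gbpl3-5 and 274 in crwn4-1 against WT, and 7 in K83A against gbpl3-5. With a minimum absolute log2 fold change of 1, 329, 378 and 682 genes were called in gbpl3-5, comp2 and crwn1-1crwn4-1 against WT, 347 in K83A against comp2, and 596 and 1074 in crwn1-1crwn4-1 against crwn4-1 and gbpl3-5. At this minimum 45 and 33 genes were shared by gbpl3-5 with crwn4-1 and crwn1-1crwn4-1, 20 by the latter mutants, and 133 by gbpl3-5 and comp2.

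With the replicate number as a block (replicate block), 252 genes were called in crwn4-1 against WT, and the other 9 counts stayed within 1.5 times; 280 of 285 named results and 82 of 86 list calls kept their side of the threshold. Of 45 pairs with the same number 21 had a correlation over 0.1 (lowest -0.255, highest 0.475), and 10 of 18 libraries correlated best with their own number. The numbers pair the libraries of crwn1-1crwn4-1 with those of crwn4-1 and of gbpl3-5, where the block gave 1147 (954) and 2404 (2064) genes and changed no list call; in the other 8 comparisons the libraries share only a number.

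Lists called by camera numbered 6, 12, 8, 11, 5, 9, 9, 10, 8 and 8 in the order of comparisons above. With an estimated correlation between genes they numbered 0, 1, 0, 0, 2, 0, 1, 0, 1 and 1. The one-direction fry test called 3, 1, 4, 1, 3, 0, 5, 0 and 3 in the first 9, and the mixed fry test called 0 in K83A, 6 in crwn4-1 and 9 in crwn1-1crwn4-1 against WT, 3 in gbpl3-5 against comp2, 2 in K83A against gbpl3-5, and 13 and 17 in crwn1-1crwn4-1 against crwn4-1 and gbpl3-5.

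With each library of the 2 compared groups left out in turn, the counts of changed genes ran from 119 to 2050, 6 to 43, 213 to 633, 5 to 240, 527 to 929, 22 to 56, 73 to 474, 3 to 828, 467 to 956 and 976 to 2635 in the order above. Without a gbpl3-5 library comp2 against WT had 714 to 889 genes, and without a comp2 library gbpl3-5 against WT had 503 to 660; other omissions outside the compared groups were not tabulated. With any of the 18 libraries left out, genes shared by gbpl3-5 with K83A ran from 6 to 31, with crwn4-1 from 2 to 149 and with crwn1-1crwn4-1 from 21 to 265, those of K83A with crwn4-1 from 0 to 2 and with crwn1-1crwn4-1 from 1 to 6, and those of crwn4-1 with crwn1-1crwn4-1 from 3 to 74. Of the genes changed in gbpl3-5, 17 to 43 were called against comp2 and 60 to 458 in comp2 against WT. Without a library of the compared groups, lists called ran from 3 to 10 in comp2 and 5 to 10 in crwn4-1 against WT, 4 to 12 and 5 to 10 in gbpl3-5 and K83A against comp2, and 5 to 8 in crwn1-1crwn4-1 against gbpl3-5, with the other 5 comparisons within 1.5 times.

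With 3 libraries against 3 there are 10 splits and the share of splits is never under 0.1. The highest count of any other split, beside the real count, was 0 for gbpl3-5, 2 for K83A, 1 for comp2, 0 for crwn4-1 and 0 for crwn1-1crwn4-1 against WT, 0 for K83A against comp2, 0 for K83A against gbpl3-5, and 40 and 6 for crwn1-1crwn4-1 against crwn4-1 and gbpl3-5, so that in each the real split alone (1 of 10) reached its count. For the last 2, whose numbers pair the libraries, these highest counts came from splits that part fewer than 3 pairs, and the highest of the other 3 splits that part as many pairs as the real one was 0 by edgeR. For gbpl3-5 against comp2, 2 of 10 splits reached 32. The other, with gbpl3-5 replicate 1, comp2 replicate 1 and comp2 replicate 3 on one side, called 4466 genes. Spearman's rho with transcript length was 0.428, 0.316 and 0.205 in these libraries. It was -0.277 and -0.486 in gbpl3-5 replicates 2 and 3 and -0.526 in comp2 replicate 2. The sides were also apart on the second principal component and in the GC trend, and which trait underlies the split was not tested.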

Other observations

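The clock lists, the neighbour test and its comparison with random genes were chosen after the data had been seen.

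Among the 32 genes that differed between gbpl3-5 and comp2, 10 also changed the same way in gbpl3-5 against WT and in K83A against comp2. A further peroxidase of this set, AT5G06730 (chosen after its values were seen), was higher by a log2 fold change of 3.17 in gbpl3-5 against WT (adjusted p = 0.00215) and of 3.77 in K83A against comp2 (adjusted p = 0.00138). The arabinogalactan protein gene AGP22, also chosen after its values were seen, was lower by log2 fold changes of -1.99 and -1.06 in the same comparisons. MRD1 was low in gbpl3-5, comp2, K83A and crwn4-1 but not in crwn1-1crwn4-1, where its 3 libraries had 44.4, 47.8 and 52.6 CPM, so its level did not follow the state of CRWN4.

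Of 18 clock genes, chosen after the data had been seen, 9 were called in crwn1-1crwn4-1 against WT. The morning genes PRR7 (log2 fold change -2.52), LNK1 (-2.85), LNK2 (-2.44), RVE7 (-1.62) and CCA1 (-2.41) and the evening genes GI (-2.47), PRR5 (-2.04) and FKF1 (-1.02) were lower, and BOA (1.43) was higher. The direct comparison of crwn1-1crwn4-1 with crwn4-1 called 8.

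A hypothesis that changed genes are grouped along chromosomes beyond tandem copies was prompted by the thalianol cluster. It was tested without the triterpene list and without neighbours that share a description or at least 3 stretches of 5 residues in their proteins. In gbpl3-5 against WT, 11 pairs of neighbouring genes were then called in the same direction, against a median of 8 in 1000 random draws matched on expression (permutation p = 0.2). In crwn1-1crwn4-1 there were 40 against 43 (permutation p = 0.7) and in comp2 18 against 15 (permutation p = 0.25), so no excess was detected in these 3 comparisons, and whether changed genes are grouped stays open.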
